A study of Mus musculus with 16 samples.

How the data were processed

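RNA of sorted splenic centroblasts and centrocytes was sequenced from TruSeq RNA libraries, in 16 libraries of 4 groups with 4 replicates each. The cells were B220 and FAS positive and CD38 negative, and were sorted into Trizol from mice of 3 months on day 8 after immunization. The deposited table holds the count of reads per gene symbol, whole numbers that are not normalized. Per the submitters' processing notes, reads were trimmed with Trim Galore and cutadapt, aligned to mm10 with STAR 2.5.3a and counted with featureCounts 1.4.5-p1 of Subread. Strand, counting settings and annotation are not given there, so counts of overlapping or antisense genes and of near-identical genes (the Bcl2a1 family, Iglc2 and Iglc3, MHC and globin genes) are uncertain. The design text also mentions naive B cells, which are not analysed here. Coordinates, lengths and GC content came from GENCODE M21 by gene symbol, for 14774 of the 15240 tested genes (96.9%). Totals ranged from 35230563 to 44466911 counted reads per library, and 19838 to 26724 genes per library had a count. PCR reads without molecular identifiers are not independent molecules, so counting precision is a lower bound on the error, and the error given is that between replicates.

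Counts were analysed in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Genes were kept by filterByExpr by group, scaled by TMM factors and fitted with the edgeR quasi-likelihood test on a model with 1 mean per group over all 16 libraries, which leaves 12 residual degrees of freedom. Adjusted p values are Benjamini-Hochberg values over all tested genes from 2-sided tests, with a threshold of 0.05. Log2 fold changes are given with the SE of the fit, and CPM values as mean ± SD of counts scaled by the TMM-adjusted library size. There were 5 comparisons: mutant against control in each cell type, centrocytes against centroblasts in each genotype, and the interaction of genotype and cell type. Gene lists of pathways and cell type markers, 36 in number, were tested with camera (preset correlation 0.01, then with the correlation estimated) and fry, and 34 had at least 5 tested members. Adjusted p values of lists are Benjamini-Hochberg values over these 34. The comparisons, lists, tests, the first group of other settings (DESeq2 and those listed with it) and the rule for naming genes were chosen before the data were examined.

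The rule named, in each comparison, the 8 largest rises and 8 largest falls among called genes with log2 CPM of at least 2 and no overlap between the groups' libraries. It added up to 4 called members per direction and 2 uncalled members of each list, the 2 highest markers of each cell type list, Ezh2 and the sort genes, and the 10 smallest p values where fewer than 10 genes were called. This gave 828 results of a gene in a comparison. The text names a part of them, chosen after their values were seen, mostly called genes that stayed called whichever library was left out, and some genes of the rule are not reported here, so the stability of the named genes is above that of all 828. Of the 477 called results among these, 354 (74.2%) stayed called with every library left out in turn, and none changed direction in that test.

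Sex was read from Y-linked transcripts. The first group of other settings was DESeq2, RLE factors, no filter, a mean of at least 1 CPM, the compared groups alone, a 1.5-fold minimum, a replicate block, immunoglobulin genes left out, the estimated correlation and each library left out. Settings added after the data were seen were sex as a covariate, an offset per library from splines (4 degrees of freedom) of GC content and transcript length, that offset together with the block, and mutant centrocyte libraries 3 and 4 left out. Pairing of same-numbered libraries was tested by the correlation of their deviations from the means of their groups. All 4 pairs of mutant libraries had a correlation above 0.1 (0.263 to 0.327), so the blocked counts stand beside that comparison, but 1 of the 4 pairs matched best by number in both directions. Xist, a transcript high in females, was 3.97 and 5.27 CPM in mutant centroblast and centrocyte libraries 1. In the other male libraries it was 0.31 to 0.754 CPM, which speaks for a shared mouse in that pair. For the other pairs the numbers are not shown to mark shared mice. A control and a mutant library cannot share a mouse, so in genotype comparisons the block joins libraries by number, and so by sex, alone. Blocked fits of 2 groups used those groups only, so their counts also reflect fewer libraries and fewer degrees of freedom. The procedure was tested on simulated counts, drawn with the mean and dispersion of each real gene and the real library sizes, with 200 genes changed per simulation. The draws held no sex difference, no GC or length trend and no correlation between genes, so the rates that follow may not carry over to the real libraries. Of genes changed 2-fold it called 58% in the centroblast comparison, 50% in the centrocyte comparison, 51.9% and 60% in the control and mutant cell type comparisons, and 40.8% in the interaction. At most 5.5% of the calls were genes left unchanged.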

Results

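Germinal centre B cells were sorted from the spleens of C57BL/6J mice, 3 months old, on day 8 after immunization with sheep red blood cells, and their RNA was sequenced. Centroblasts, the cycling cells of the dark zone, were taken as CXCR4 positive and CD86 negative, and centrocytes, the light zone cells that test their receptors, as CXCR4 negative and CD86 positive. The mutant mice carried 1 conditional Ezh2 allele with the Y641F change found in germinal centre lymphoma, switched on by Cγ1-cre, and the controls carried Cγ1-cre alone. Each of the 4 groups (control and mutant centroblasts, control and mutant centrocytes) had 4 libraries, taken as biological replicates. The libraries held 35230563 to 44466911 counted reads each. Of 49492 listed genes 32898 had a count, and 15240 had enough to be tested. Y-linked transcripts showed that libraries 1 and 2 of every group came from males and libraries 3 and 4 from females.

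The cell type separated the libraries along the first principal component, with 28.1% of the variance, and the genotype along the next, with 21.7%. Cxcr4, the receptor used for the dark zone gate, averaged 444 ± 17.0 CPM (counts scaled by the TMM-adjusted library size; SD, n = 4) in control centroblasts and 197 ± 10.9 CPM in control centrocytes. Cd86, the light zone gate marker, averaged 145 ± 37.7 and 280 ± 40.8 CPM in the same groups. In mutants Cxcr4 averaged 401 ± 20.9 and 160 ± 23.6 CPM, and Cd86 163 ± 23.3 and 311 ± 57.4 CPM. These genes served the sort, so they check the gate and nothing more. Between genotypes neither passed the edgeR test: Cxcr4 differed by −0.15 ± 0.10 (log2, SE) in centroblasts (adjusted p = 0.432) and by −0.30 ± 0.10 in centrocytes (adjusted p = 0.0526), and Cd86 by 0.17 ± 0.17 and 0.15 ± 0.17 (adjusted p = 0.624 and 0.597). The difference of Cxcr4 in centrocytes did pass in DESeq2 (adjusted p = 0.0275) and in edgeR without mutant library 4 (0.0316), with genes of at least 1 CPM (0.034), without immunoglobulin genes (0.0433) and with an offset for GC content and length (0.0317).

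**Figure D1:**
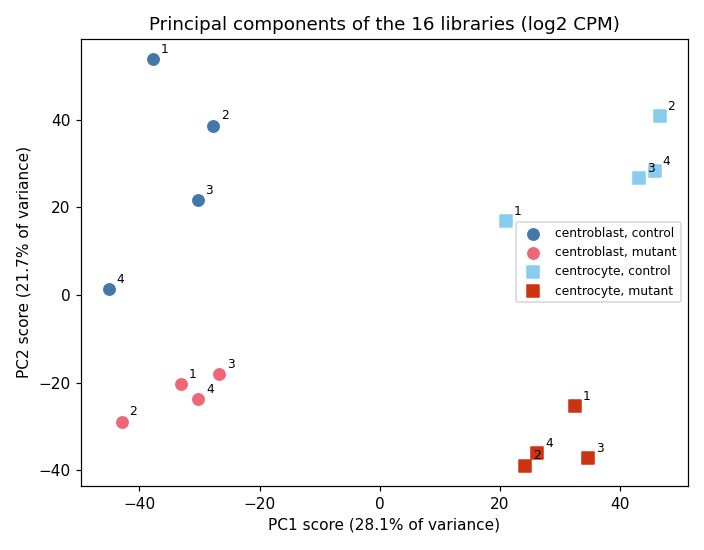
Scores of the 16 libraries on the first 2 principal components of log2 CPM, with 28.1% and 21.7% of the variance; circles are centroblasts, squares are centrocytes, colours give the genotype and numbers the replicate. Mutant libraries lie between −18.1 and −39.0 on the vertical axis and control libraries at 16.8 or above, except control centroblast library 4 at 1.39.

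Ezh2, the histone methyltransferase of Polycomb repressive complex 2, was slightly lower in mutants of both cell types. In centroblasts it averaged 289 ± 42.0 CPM in controls and 222 ± 32.0 CPM in mutants (SD, n = 4), a log2 fold change of −0.38 ± 0.12 (SE, adjusted p = 0.0486). In centrocytes the means were 245 ± 15.0 and 189 ± 15.2 CPM, a change of −0.37 ± 0.12 (adjusted p = 0.0395). In the mm10 genome Ezh2 lies on chromosome 6 from 47530139 to 47595341, on the minus strand. The gene count does not tell the mutant from the wild-type allele. Both calls hung on single libraries and on the settings. In centroblasts the adjusted p was 0.119, 0.113 and 0.0818 without control library 1, 2 or 3, and 0.0661, 0.1 and 0.138 without mutant library 1, 3 or 4. In centrocytes it was 0.0621, 0.0784 and 0.1 without control library 1, 2 or 4, and 0.0909 and 0.0974 without mutant library 2 or 4, and 0.157 without mutant libraries 3 and 4. With the replicate block the adjusted p was 0.0755 in centroblasts and 0.0561 in centrocytes, without the filter 0.0901 and 0.062, and in centroblasts with the compared groups alone 0.155.

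The genotype comparison in centroblasts asks what the mutant methyltransferase changes in cycling germinal centre B cells. Smad1, a transducer of BMP signals, fell the most among the named genes, 6.37-fold (log2 fold change −2.67 ± 0.21, SE, n = 4 per group, adjusted p = 1.24e-06), and Lgr5, an R-spondin receptor, fell from 28.4 ± 3.34 to 5.77 ± 0.283 CPM. Smad1 lies on chromosome 8 from 79338395 to 79399518 and Lgr5 on chromosome 10 from 115450311 to 115587780. Raph1 (lamellipodin, an actin regulator) and Cers6 (a ceramide synthase) fell by 2.48 ± 0.28 and 2.37 ± 0.25 on the log2 scale. Atxn1, a transcriptional corepressor, rose from 1.32 ± 0.299 to 7.01 ± 0.566 CPM, or 5.32-fold; it lies on chromosome 13 from 45549755 to 45965008. Tnfrsf18 (the costimulatory receptor GITR) rose by 2.04 ± 0.22 and the myosin gene Myo1f by 1.98 ± 0.14. The chemokine receptor gene Cxcr3 rose from 15.0 ± 1.19 to 40.8 ± 3.65 CPM. Gpr183, the oxysterol receptor EBI2 that positions B cells at the follicle edge, rose by 1.36 ± 0.16 (adjusted p = 3.32e-05). Dnmt3a, a DNA methyltransferase, rose from 19.4 ± 3.87 to 38.7 ± 4.17 CPM. In all, 619 genes were higher and 976 lower in mutants, of which 140 and 414 changed at least 2-fold. The libraries of the compared groups did not overlap for 14.4% of the tested genes, where chance gives 2.86%. Among males alone 1318 genes were higher and 1153 lower, among females alone 226 and 409, with 2 libraries per group in each. The male and female changes had a Spearman correlation of 0.172 across genes, which are not independent replicates (0.321 with an offset for GC content and length). The count of higher genes was 381 without control library 2 and 411 without mutant library 4. With the replicate block 272 genes were higher and 599 lower, with the compared groups alone 354 were higher, and with the GC and length offset 1382 were higher and 1457 lower.

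Genes of DNA replication and mitosis were lower in mutant centroblasts. Of 31 replication genes 10 fell and none rose (19 fell when adjusted over the list alone; camera adjusted p = 4.78e-10, adjusted p = 0.172 with an estimated correlation). Among them were Cdc6, which loads the replicative helicase (−0.49 ± 0.085), Cdc45, a part of that helicase (−0.44 ± 0.10), and the ribonucleotide reductase gene Rrm2 (−0.44 ± 0.089). Of 32 mitosis genes 5 fell (12 when adjusted over the list alone; camera adjusted p = 1.22e-06, adjusted p = 0.172 with an estimated correlation), Prc1 of the spindle midzone among them (−0.37 ± 0.090). The adjusted p of Prc1 was 0.0733 without the filter, 0.0711 with the compared groups alone and 0.084 with the replicate block, and that of Rrm2 was 0.0544 with the block. Of 18 genes of somatic hypermutation and class switching 4 fell (4 fell and 1 rose when adjusted over the list alone), including the mismatch repair genes Exo1 (−0.49 ± 0.093) and Msh6 (−0.53 ± 0.11). This list had an adjusted p of 0.0476 (adjusted p = 0.65 with an estimated correlation), and its adjusted p was 0.138 or 0.0574 without control library 1 or 2 and 0.0653, 0.0527 or 0.0706 without mutant library 2, 3 or 4. It was 0.0602 with the replicate block, 0.0575 with sex as a covariate and 0.368 with the GC and length offset.

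Lists of CD40 and NF-kB signalling and of contact with T follicular helper cells were higher in mutant centroblasts by camera with the preset correlation. Neither passed with an estimated one. Of 25 CD40 and NF-kB targets 5 rose (5 when adjusted over the list alone), such as Ebi3, a subunit of interleukin 27 (1.51 ± 0.21), and Nfkb1 (0.46 ± 0.097). The adjusted p of the list was 0.00383 (adjusted p = 0.65 with an estimated correlation) and 0.0501 without control library 1. By fry the CD40 list did not pass (adjusted p = 0.0581). Of 24 contact genes 3 rose, among them Il6ra, the interleukin 6 receptor chain (0.92 ± 0.13). The list gave 3 when adjusted over the list alone (adjusted p = 0.00383, adjusted p = 0.438 with an estimated correlation). By fry the contact list passed (adjusted p = 0.0115). Markers of naive follicular B cells moved with these lists: of 17, 3 rose (4 when adjusted over the list alone; adjusted p = 0.0476, adjusted p = 0.65 with an estimated correlation). Their adjusted p was 0.0696 or 0.051 without control library 3 or 4, 0.258 or 0.0706 without mutant library 3 or 4, 0.0598 with the replicate block and 0.0755 with genes of at least 1 CPM. By edgeR 0 of 12 genes of MHC class II presentation passed the test alone (2 rose when adjusted over the list alone, 7 were higher at an unadjusted p under 0.05, and DESeq2 called 2), while the list as a whole was higher (adjusted p = 0.000271, adjusted p = 0.61 with an estimated correlation). Its member H2-Aa averaged 2719 CPM in controls and 3502 CPM in mutants, a difference of 0.37 ± 0.12 (adjusted p = 0.0543). The adjusted p of H2-Aa was 0.0241 without control library 4, 0.0451 without mutant library 1, 0.0154 by DESeq2, 0.0423 with genes of at least 1 CPM, 0.0365 with sex as a covariate and 0.018 with the GC and length offset. Of 20 p53 targets 4 fell and 1 rose (5 and 1 when adjusted over the list alone), and the list did not pass in camera (adjusted p = 0.272), while fry, which does not compare it with other genes, gave it an adjusted p of 0.0184. Sesn1 (sestrin, −0.99 ± 0.12) and the RNA-binding gene Zmat3 (−0.82 ± 0.12) were among those that fell, and Plk3 rose (0.82 ± 0.17). Bcl2l11 (BIM, −0.67 ± 0.15) and Pmaip1 (NOXA, −0.82 ± 0.19), activators of cell death, fell as well, but their list did not pass (3 of 16 fell, 3 when adjusted over the list alone; adjusted p = 0.697).

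In centrocytes the same comparison asks what the mutation changes in light zone cells. Lgr5 fell 10.2-fold, from 9.06 ± 1.46 to 0.885 ± 0.251 CPM (log2 fold change −3.35 ± 0.19, SE, n = 4 per group, adjusted p = 2.31e-08). Raph1 (−3.12 ± 0.28), Smad1 (−2.96 ± 0.21) and Map2 (a microtubule-binding protein, −2.55 ± 0.32) followed. Tox, a chromatin-binding factor of lymphocytes, fell from 62.2 ± 7.89 to 13.1 ± 2.51 CPM, and Dusp5, a phosphatase that restrains ERK, fell by 1.09 ± 0.12. The adhesion gene Cadm1 rose by 1.98 ± 0.24 (adjusted p = 5.36e-05), the creatine kinase gene Ckb by 1.82 ± 0.28, and the retinal reductase gene Dhrs3 by 1.49 ± 0.16. The chemokine receptor genes Cxcr3 and Ccr6 rose by 1.53 ± 0.14 and 1.26 ± 0.21. In total 1123 genes were higher and 1394 lower in mutants, 186 and 579 of them at least 2-fold. The groups did not overlap for 23.5% of tested genes, where chance gives 2.86%. Males alone gave 1059 genes, 418 of them higher, and females alone 1087 higher and 1120 lower, with 2 libraries per group and a Spearman correlation of 0.487 between the changes. The count of higher genes was between 619 and 675 without control library 2, 3 or 4 and 733 without mutant library 2. With mutant libraries 3 and 4 both left out, as described with the macrophage markers, 495 genes were higher and 729 lower. With an offset for GC content and length the balance turned, to 2139 higher and 2003 lower.

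Mitosis genes were lower in mutant centrocytes. Of 32 members 21 fell and none rose (30 fell when adjusted over the list alone; camera adjusted p = 7.39e-13, adjusted p = 0.0259 with an estimated correlation). They included Ccna2 (cyclin A, −0.59 ± 0.12), Nek2 (a centrosome kinase, −0.59 ± 0.12), Cdc25c (a phosphatase that starts mitosis, −0.53 ± 0.11) and Ube2c (−0.51 ± 0.10). The proliferation marker Mki67 differed by −0.74 ± 0.26 with an edgeR adjusted p of 0.0624, and 0.0487 without mutant library 1. It was called by DESeq2 (adjusted p = 0.0303) and by edgeR without the filter (0.00266), with the compared groups alone (0.00516), with the replicate block (0.00597) and with sex as a covariate (0.0369). Of 31 replication genes 6 fell (6 when adjusted over the list alone), Cdc6 (−0.42 ± 0.085) and the polymerase gene Pole (−0.49 ± 0.10) among them. That list had an adjusted p of 0.00163 (adjusted p = 0.81 with an estimated correlation), and 0.0832 without control library 1.

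Genes of oxidative phosphorylation and of MHC class II presentation were higher in mutant centrocytes. Of 36 oxidative phosphorylation genes 12 rose and none fell (20 rose when adjusted over the list alone; camera adjusted p = 3.05e-08, adjusted p = 0.81 with an estimated correlation), with Ndufb5 of complex I as an example (0.50 ± 0.12, adjusted p = 0.0067). Of 12 MHC class II genes 6 rose (8 when adjusted over the list alone; adjusted p = 0.000601, adjusted p = 0.81 with an estimated correlation), including the class II alpha chain gene H2-Aa (0.64 ± 0.12) and the protease gene Ctss (0.59 ± 0.13). Macrophage markers, high in mutant libraries 3 and 4, moved with them (median log2 fold change 0.93). Without these libraries both lists passed at the preset correlation, but Ctss changed by 0.38 (adjusted p = 0.0824) and Ndufb5 by 0.44 (adjusted p = 0.0563). Genes higher in mutant centrocytes had a median transcript length of 2244 bases and lower genes 3841. The change had a Spearman correlation of −0.228 with length across genes, which are not independent replicates, and of −0.19 in centroblasts. Both lists passed with the GC and length offset too, at the preset correlation. Ribosomal protein genes took 1.82 ± 0.179% of counts in control and 2.59 ± 0.505% in mutant centrocytes (SD, n = 4; exact permutation test, 70 splits, 2-sided p = 0.0286, the smallest these splits allow, and 0.571 after adjustment over 20 tests). Of 17 naive follicular B cell markers 4 rose (4 when adjusted over the list alone), and the list did not pass (adjusted p = 0.113).

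Other named genes of mutant centrocytes went both ways. Cd79a and Cd79b, the signalling chains of the B cell receptor, rose by 0.50 ± 0.12 and 0.55 ± 0.12, and the follicle homing receptor gene Cxcr5 by 0.53 ± 0.11. They are the 3 that rose among 25 germinal centre B cell regulators, of which 4 fell (3 and 5 when adjusted over the list alone), and that list did not pass (adjusted p = 0.796). Ltb (lymphotoxin beta, 0.80 ± 0.18) and Ly9 of the SLAM family (0.50 ± 0.092) rose too. Bcl2l11 fell by 1.05 ± 0.15 and Bach2, a repressor of plasma cell fate, by 0.54 ± 0.15, while Bmf, another activator of cell death, rose by 0.80 ± 0.15. The list of such activators did not pass (2 of 16 rose and 2 fell, also when adjusted over the list alone; adjusted p = 0.604). Of 21 memory B cell genes 5 rose, Ccr6, Cxcr3, Gpr183 and Ltb among them, and 3 fell, Zeb2 and Bach2 among them (5 and 3 when adjusted over the list alone). The list did not pass (adjusted p = 0.604), with a median of −0.050 and a mean of 0.092. Igha, the IgA constant region, fell by 2.46 ± 0.38. Iglc2 rose by 0.99 ± 0.14, though its reads cannot be told from those of the near-identical Iglc3.

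Macrophage markers stood apart in mutant centrocyte libraries 3 and 4. The summed level of the 18 markers that averaged under 20 CPM was 325 and 321 CPM in these libraries and 41.3 to 124 CPM in the other centrocyte libraries. The remaining markers Apoe and Ctsb averaged 415 ± 37.2 and 168 ± 8.83 CPM in control centrocytes and 732 ± 42.8 and 276 ± 64.2 CPM in mutants (log2 fold changes 0.82 ± 0.18 and 0.72 ± 0.15; adjusted p = 0.0058 and 0.00294). Of the 20 markers 3 rose and 1 fell, also when adjusted over the list alone, and the list did not pass (adjusted p = 0.148).

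**Figure D2:**
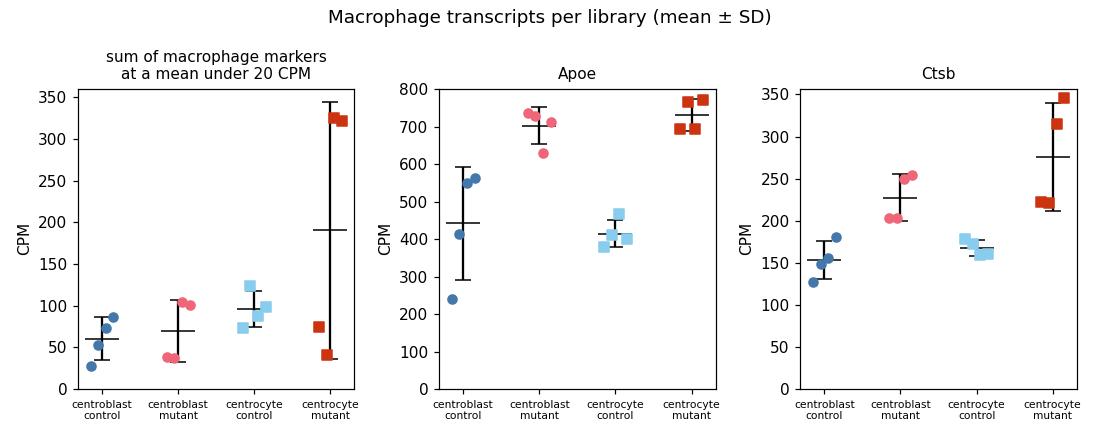
CPM per library of the summed low macrophage markers, Apoe and Ctsb in the 4 groups, with the mean ± SD (n = 4). Mutant centrocyte libraries 3 and 4 lie at 325 and 321 CPM in the marker sum, and Apoe averages 732 CPM in mutant against 415 CPM in control centrocytes.

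**Figure D3:**
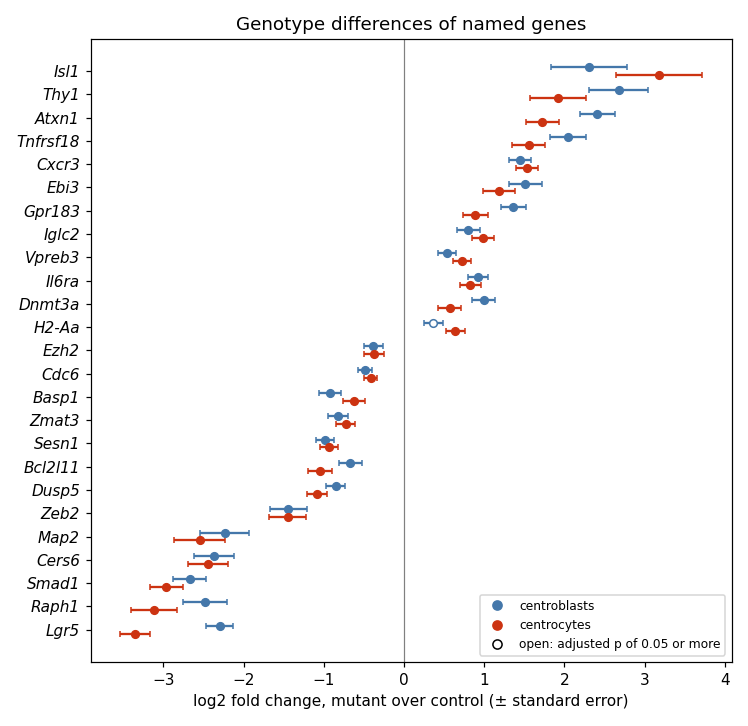
Log2 fold change of mutant against control ± SE for named genes in centroblasts (blue) and centrocytes (red), n = 4 per group; open symbols mark an adjusted p of 0.05 or more. Lgr5 lies at −2.30 and −3.35 and Atxn1 at 2.41 and 1.72, and H2-Aa in centroblasts is the only open symbol.

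The genotype changes in centroblasts and centrocytes overlapped. Genes higher in both numbered 441, against 45.6 for independent lists, and genes lower in both 771 against 89.3. With the replicate block these counts were 211 and 508, and with the GC and length offset 1053 and 1105. No gene was called in opposite directions by edgeR, where independent lists would give 129 and DESeq2 gave 1. At an unadjusted p under 0.05 in both there were 8. Across genes, which are not independent replicates, the changes had a Spearman correlation of 0.712. Shared rises included Atxn1 (2.41 and 1.72), Tnfrsf18 (2.04 and 1.55), Ebi3 (1.51 and 1.19), Gpr183 (1.36 and 0.89) and Il6ra (0.92 and 0.83). Shared falls included Cers6 (−2.37 and −2.44), Zeb2, a zinc finger factor (−1.44 and −1.45), Sesn1 (−0.99 and −0.93) and Zmat3 (−0.82 and −0.73). The cell types share no libraries but may share mice.

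The test of the difference between these changes, the interaction of genotype and cell type, called no gene. Vav3, a guanine nucleotide exchange factor, had an estimate of −1.90 ± 0.38 (log2, SE), Lgr5 −1.05 ± 0.25 and Myo1f −0.87 ± 0.19, each with an adjusted p of 0.999. The edgeR count was 0 in both directions, with 429 genes at an unadjusted p under 0.05 where 762 are expected by chance. DESeq2 called Vav3 alone (adjusted p = 0.0324), with 604 genes at an unadjusted p under 0.05. As a list, mitosis genes had a more negative genotype change in centrocytes than in centroblasts (camera adjusted p = 3.33e-07, adjusted p = 0.196 with an estimated correlation). Oxidative phosphorylation genes had a more positive one (adjusted p = 2.6e-06, adjusted p = 0.808 with an estimated correlation), and so did replication genes (adjusted p = 0.000895, adjusted p = 0.808 with an estimated correlation). No list passed for the interaction with an estimated correlation or by fry.

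The comparison of centrocytes with centroblasts in control mice asks how the zones of the germinal centre differ. Ccr6, a chemokine receptor of memory precursors, rose 8.53-fold in centrocytes, from 4.78 ± 1.16 to 40.8 ± 6.85 CPM (log2 fold change 3.09 ± 0.23, SE, n = 4 per group, adjusted p = 8.35e-08). Ccr6 lies on chromosome 17 from 8236043 to 8257141 and Ret on chromosome 6 from 118151745 to 118197718. The scaffold gene Shank1 rose by 4.18 ± 0.27, the meiotic cohesin gene Rec8 by 3.11 ± 0.29, and Il4i1, an amino acid oxidase, by 2.89 ± 0.21. The receptor tyrosine kinase gene Ret fell by 3.16 ± 0.21, the cell cycle regulator Rgcc by 2.42 ± 0.15, and Gcsam, a motility regulator of germinal centre B cells, by 1.90 ± 0.13. Cxcr4 fell by 1.17 ± 0.10 and Cd86 rose by 0.95 ± 0.18, as the gate sets. Cd38, which the gate excluded in both cell types, rose by 1.07 ± 0.22. Ezh2 differed by −0.24 ± 0.12 (adjusted p = 0.149), and by −0.33 (adjusted p = 0.0404) without control centroblast library 4. In all 2270 genes were higher and 1960 lower in centrocytes, 949 and 322 of them at least 2-fold. The groups did not overlap for 27.7% of tested genes, where chance gives 2.86%. Males alone gave 1506 higher and 928 lower genes and females alone 2044 and 1690, with 2 libraries per group. With an offset for GC content and length the balance turned, to 2736 higher and 3148 lower.

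Several gene lists were higher in control centrocytes, some of them with the preset correlation alone. Of 25 CD40 and NF-kB targets 21 rose and 1 fell (21 and 1 when adjusted over the list alone; camera adjusted p = 1.55e-12, adjusted p = 0.0353 with an estimated correlation), such as Cd83, a light zone surface marker (1.61 ± 0.11), and Nfkbid, a nuclear regulator of NF-kB (2.34 ± 0.18). Of 16 early genes of B cell receptor signalling 11 rose and 1 fell (13 and 1 when adjusted over the list alone; adjusted p = 2.9e-07, adjusted p = 0.142 with an estimated correlation), including Egr3 (3.07 ± 0.23), Egr2 (2.54 ± 0.21) and Nr4a1 (2.01 ± 0.19). Of 24 genes for contact with T follicular helper cells 14 rose and 1 fell (14 and 2 when adjusted over the list alone; adjusted p = 1.67e-06, adjusted p = 0.0353 with an estimated correlation), Cd72 (1.45 ± 0.12) and Slamf1 (1.26 ± 0.11) among them. Of 10 anti-death genes 8 rose (8 when adjusted over the list alone; adjusted p = 6.32e-05, adjusted p = 0.0353 with an estimated correlation), Bcl2 by 1.95 ± 0.19 and Birc3 by 0.63 ± 0.083. Of 28 MYC targets and ribosome biogenesis genes 10 rose (11 rose and 1 fell when adjusted over the list alone; adjusted p = 8.73e-05, adjusted p = 0.258 with an estimated correlation), with Gnl3 at 1.05 ± 0.15 and Polr1b at 1.04 ± 0.096, and Myc itself rose by 1.47 ± 0.20. Of 12 MHC class II genes 9 rose (10 when adjusted over the list alone; adjusted p = 1.66e-05, adjusted p = 0.216 with an estimated correlation), with Ifi30 at 1.18 ± 0.14 and H2-DMb1 at 1.04 ± 0.13. Of 21 memory B cell genes 11 rose and 3 fell (13 and 4 when adjusted over the list alone; adjusted p = 0.00223, adjusted p = 0.354 with an estimated correlation), with Hhex 5.64-fold higher and the IgE receptor gene Fcer2a at 2.07 ± 0.14. The lymphotoxin and TNF genes Lta (1.06 ± 0.12) and Tnf (1.18 ± 0.14) rose too. Markers of naive follicular B cells were higher as well: of 17, 7 rose and 1 fell (9 and 1 when adjusted over the list alone; adjusted p = 0.000199, adjusted p = 0.097 with an estimated correlation).

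Proliferation genes fell in control centrocytes. Of 32 mitosis genes 22 fell (25 when adjusted over the list alone; camera adjusted p = 8.86e-16, adjusted p = 0.0113 with an estimated correlation), such as Ccnb2 (cyclin B, −1.22 ± 0.11), Kif20a (a kinesin of cell division, −0.95 ± 0.096) and Cenpa (the centromeric histone, −0.83 ± 0.088). Of 31 replication genes 21 fell (22 when adjusted over the list alone; adjusted p = 1.5e-09, adjusted p = 0.0942 with an estimated correlation), with Mcm6, a helicase subunit, at −0.70 ± 0.11. Of 36 oxidative phosphorylation genes 26 fell (28 when adjusted over the list alone; adjusted p = 4.54e-10, adjusted p = 0.278 with an estimated correlation), with Atp5a1 at −0.60 ± 0.11 and Uqcrfs1 at −0.57 ± 0.089. Of 18 hypermutation and switching genes 7 fell and 1 rose, also when adjusted over the list alone, including Polh, an error-prone polymerase (−1.49 ± 0.088). That list had an adjusted p of 0.028 (adjusted p = 0.502 with an estimated correlation), 0.0744 without control centroblast library 1, 0.0576 with the replicate block and 0.0501 with genes of at least 1 CPM.

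In mutant mice the zones differed in many of the same named genes. Ccr6 rose 11-fold in centrocytes (log2 fold change 3.46 ± 0.23, SE, n = 4 per group, adjusted p = 3.73e-08), Rec8 by 3.40 ± 0.28, Shank1 by 3.02 ± 0.26 and Il4i1 by 2.64 ± 0.21. Ret fell by 3.75 ± 0.22, Lgr5 by 2.70 ± 0.19, Rgcc by 2.67 ± 0.15 and Gcsam by 1.97 ± 0.13. Cxcr4 fell by 1.32 ± 0.10, Cd86 rose by 0.93 ± 0.18 and Cd38 by 1.30 ± 0.22. Zeb2 rose by 1.45 ± 0.24 in mutant centrocytes over mutant centroblasts. In total 1360 genes were higher and 1078 lower, 535 and 289 of them at least 2-fold. With same-numbered libraries paired by a replicate block, 2099 were higher and 1477 lower. The labels do not state a shared mouse, but same-numbered mutant libraries matched in sex and had correlations of 0.263 to 0.327. The groups did not overlap for 22.1% of tested genes, where chance gives 2.86%. Males alone gave 969 higher and 665 lower genes and females alone 672 and 515, with 2 libraries per group. With the GC and length offset the balance turned here too, to 1916 higher and 2188 lower. Against the control comparison 1142 genes were higher in both (203 for independent lists), 904 lower in both (139), and 0 opposite by edgeR (335), with 7 at an unadjusted p under 0.05 and 0 by DESeq2. The Spearman correlation was 0.777 across genes; the test of the difference is the interaction given above.

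Against mutant centroblasts, the gene groups of mutant centrocytes moved as follows. These are differences between the zones within mutants, not between genotypes. Of 25 CD40 and NF-kB targets 20 rose and 1 fell (20 and 1 when adjusted over the list alone; camera adjusted p = 2.2e-14, adjusted p = 0.0236 with an estimated correlation), with Cd83 at 1.69 ± 0.11, Nfkbid at 1.96 ± 0.18 and Cd40 at 1.02 ± 0.12. Of 12 MHC class II genes 10 rose (11 when adjusted over the list alone; adjusted p = 2.36e-08, adjusted p = 0.0655 with an estimated correlation), with H2-Aa at 0.62 ± 0.12 and Ifi30 at 1.16 ± 0.14. Of 24 genes for T follicular helper contact 14 rose and 1 fell (15 and 1 when adjusted over the list alone; adjusted p = 4.43e-08, adjusted p = 0.0177 with an estimated correlation), with Cd72 at 1.24 ± 0.12 and Slamf1 at 1.26 ± 0.11. Of 16 B cell receptor early genes 9 rose and 1 fell (11 and 1 when adjusted over the list alone; adjusted p = 1.32e-07, adjusted p = 0.114 with an estimated correlation), with Egr3 at 2.40 ± 0.22, Egr2 at 1.94 ± 0.21 and Nr4a1 at 1.80 ± 0.19. Of 10 anti-death genes 6 rose (8 when adjusted over the list alone; adjusted p = 1.42e-05, adjusted p = 0.0177 with an estimated correlation), with Bcl2 at 1.81 ± 0.19 and Birc3 at 0.43 ± 0.083. Of 21 memory B cell genes 8 rose and 3 fell (10 and 4 when adjusted over the list alone; adjusted p = 0.000694, adjusted p = 0.267 with an estimated correlation), with Hhex at 2.24 ± 0.18 and Fcer2a at 1.88 ± 0.14. Of 17 naive follicular B cell markers 7 rose and 1 fell (12 and 1 when adjusted over the list alone; adjusted p = 2.22e-06, adjusted p = 0.0321 with an estimated correlation). Of 28 MYC and ribosome biogenesis genes 3 rose (3 when adjusted over the list alone; adjusted p = 0.00255, adjusted p = 0.396 with an estimated correlation), Gnl3 at 0.71 ± 0.15 and Polr1b at 0.69 ± 0.096 among them, and Myc rose by 1.08 ± 0.20. Of 22 genes for follicular dendritic cell contact and adhesion 6 rose and 1 fell (8 and 1 when adjusted over the list alone; adjusted p = 0.00285, adjusted p = 0.165 with an estimated correlation). Of 20 macrophage markers 3 rose (12 when adjusted over the list alone; adjusted p = 0.00532, adjusted p = 0.623 with an estimated correlation), and the adjusted p was 0.0794 or 0.0947 without mutant centrocyte library 3 or 4, which held the high marker sums, and 0.674 in the other direction without both.

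Of 32 mitosis genes 27 fell in mutant centrocytes against mutant centroblasts (31 when adjusted over the list alone; camera adjusted p = 9.53e-30, adjusted p = 0.000635 with an estimated correlation), with Ccnb2 at −1.54 ± 0.11, Ube2c at −1.37 ± 0.10, Kif20a at −1.13 ± 0.097 and Cenpa at −1.13 ± 0.089. Of 31 replication genes 10 fell (15 when adjusted over the list alone; adjusted p = 1.32e-07, adjusted p = 0.114 with an estimated correlation), with Mcm6 at −0.53 ± 0.11. Of 36 oxidative phosphorylation genes 5 fell (4 when adjusted over the list alone; adjusted p = 1.46e-06, adjusted p = 0.396 with an estimated correlation), with Atp5a1 at −0.49 ± 0.11. Of 18 hypermutation and switching genes 5 fell and 1 rose (6 and 1 when adjusted over the list alone), with Polh at −1.29 ± 0.088. The adjusted p of that list was 0.0497 (adjusted p = 0.512 with an estimated correlation), 0.0902 or 0.0593 without mutant centroblast library 1 or 3, and 0.0665 or 0.0763 without mutant centrocyte library 2 or 3. It was 0.0791 with the replicate block, 0.0933 with the GC and length offset, 0.0581 with sex as a covariate, 0.0757 with genes of at least 1 CPM and 0.0727 without mutant centrocyte libraries 3 and 4.

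**Figure D4:**
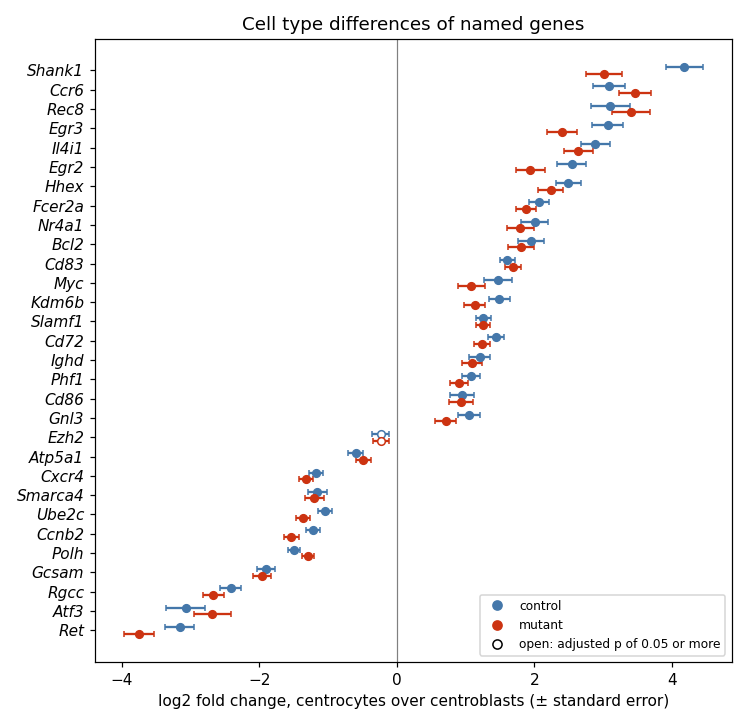
Log2 fold change of centrocytes against centroblasts ± SE for named genes in control (blue) and mutant (red) mice, n = 4 per group; open symbols mark an adjusted p of 0.05 or more, as for Ezh2. Ccr6 lies at 3.09 and 3.46 and Ret at −3.16 and −3.75.

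**Figure D5:**
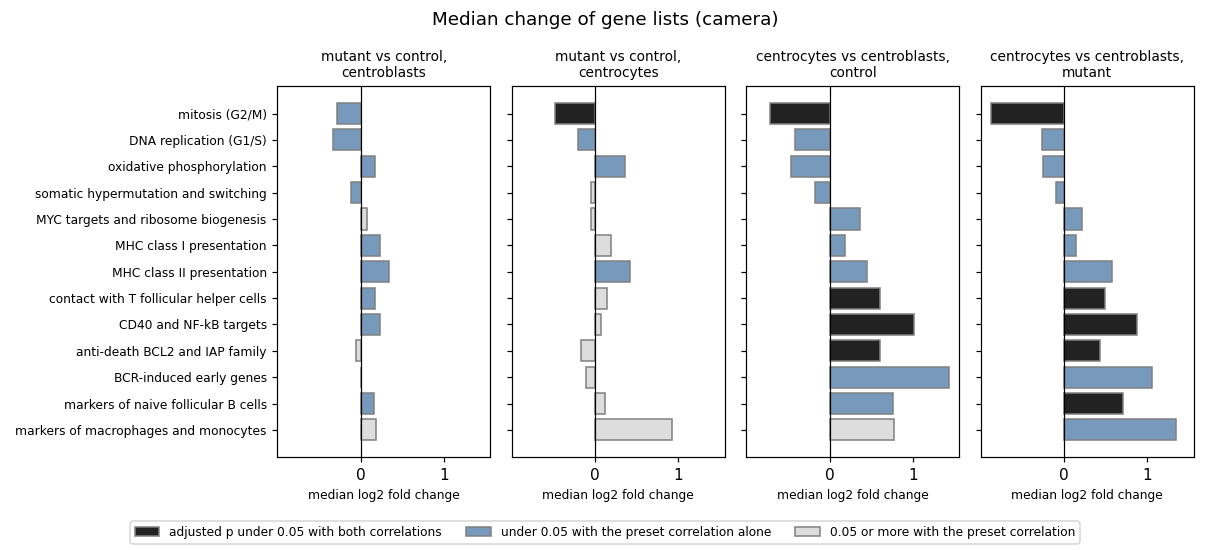
Median log2 fold change of the tested members of 13 gene lists in the 4 comparisons, n = 4 libraries per group; black points had a camera adjusted p under 0.05 with both the preset and the estimated correlation, blue points with the preset one alone, and grey points with neither. Mitosis genes are black in 3 of the 4 comparisons and blue in the genotype comparison of centroblasts.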

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

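The tests that set other splits of the libraries beside the real one were chosen beforehand; those of GC content and length, of abundant genes, of the gate and of macrophage RNA, and the sex comparison were chosen after the results were seen.

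The rises of Atxn1, Tnfrsf18 and Cxcr3 and the falls of Smad1, Raph1 and Lgr5 belonged to 1595 called genes in centroblasts and 2517 in centrocytes. Of 35 splits 1, the real one, gave as many genes in either cell type, and the other splits gave at most 0. This argues against chance, but the share of 2.86% is the smallest that 35 splits allow. The other splits mix the genotypes within each group, which widens the spread and lowers their counts. Anything that differed along with the genotype would pass this test too. Trends with GC content and transcript length are argued against as the whole cause, since 96.5% of the centroblast calls and 94.2% of the centrocyte calls were kept in the same direction with those trends taken out. The 10 most abundant genes took more of the counts in mutants, which would shift all other genes by −0.0149 and −0.0258 on the log2 scale. The smallest called changes were 0.264 and 0.25. TMM factors already take out a shift common to most genes, and such a shift cannot give calls in both directions. That comparison therefore adds nothing for the genotype. The genotype remains as a candidate explanation, a hypothesis found and tested on the same data.

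Mitosis and replication genes such as Cdc6, Prc1, Ccna2 and Nek2 were lower in mutants of one or both cell types. Centrocytes in the mutant centroblast gate as the whole cause would have to make up 40.4% or 51.4% of the cells for the mitosis list and 89.9% or 77.4% for the replication list, by 2 splits of the controls, and at the former shares the 200 genes that rise most towards centrocytes would gain a median of 0.918 or 1.06, while they gained 0.234 and no mutant library exceeded 0.365 or 0.218. A smaller share stays open for part of the change. In the centrocyte gate the fall would need a control gate with 30.9% or 31.8% centroblasts and a mutant gate without them, which would raise those genes by 0.374 or 0.406, while their median was −0.083 and no mutant library exceeded −0.0289 or 0.0867, although the 200 genes that fall most had a median of −0.174, the direction that this explanation gives, so a smaller share stays open here too. With GC and length trends taken out the mitosis list had a preset-correlation adjusted p of 5.18e-06 in centroblasts and 4.9e-13 in centrocytes. With the trends left in, camera with an estimated correlation gave it 0.172 and 0.0259, and fry gave 0.00251 and 9.18e-06. The cell types are not shown to differ in this, as the interaction of the list did not pass with an estimated correlation. A slower cell cycle was not tested, and neither gate test covers a change in cycle phase within the gate.

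Macrophage markers such as C1qa, Vcam1 and Hmox1 were high in mutant centrocyte libraries 3 and 4 (325 and 321 CPM in sum). RNA of macrophages is a candidate source, although a B220 gate should remove such cells. The markers under 20 CPM varied together within groups with a median pairwise correlation of 0.83. That value includes the 2 libraries that raised the question, so it adds no separate support. In mutant centroblasts libraries 3 and 4 also stood above 1 and 2 (104 and 100 against 38.5 and 37.3 CPM), with control centroblasts at 28.1 to 86.5 CPM. For Apoe macrophage RNA is argued against, because 101% of its change in centrocytes was left without mutant centrocyte libraries 3 and 4 (0.82 before and after, adjusted p = 0.0419). For Ctsb 57% was left (0.72 before, 0.41 after, edgeR adjusted p = 0.0874). In mutant centrocyte libraries 1 and 2 the marker sums were 74.2 and 41.3 CPM, against 72.8 to 124 CPM in control centrocytes. Ctsb stood there at 222 and 221 CPM, against 159 to 178 CPM in controls. These values argue against macrophage RNA as the whole cause for Ctsb. For the rest of its change macrophage RNA and a change in B cells cannot be told apart. Both libraries came from females, and no biological explanation was tested.

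In the cell type comparisons 1 of 35 splits, the real one, likewise gave as many genes in controls (4230, highest other 2) and in mutants (2438, highest other 18, from the split of males against females). This argues against chance with the limits given above for such splits. For the interaction of genotype and cell type the splits test nothing, as the real count of 0 is met by all 100 drawn splits whatever they give. The highest other, 4217, came from labels that swap the genotype of the centrocytes alone, a structure of the samples.

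For a difference of the genotype change between cell types, camera with the preset correlation called 6 lists. The adjusted p was 3.33e-07 for mitosis genes, 2.6e-06 for oxidative phosphorylation genes and 0.000895 for replication genes. MYC and ribosome biogenesis genes had 0.00585, CD40 and NF-kB targets 0.0204 and B cell receptor early genes 0.0261. With an estimated correlation the 6 adjusted p values were 0.196 for mitosis, 0.81 for B cell receptor early genes and 0.808 for the others. By fry 0 of the 6 passed, so a difference between the cell types is not shown for these lists. The adjusted p of the MYC list was 0.113 without control centroblast library 1 and 0.26 without control centrocyte library 1. That of the CD40 list was 0.408 or 0.175 without control centroblast library 1 or 2, 0.066 without mutant centroblast library 4, 0.0985 or 0.0605 without control centrocyte library 1 or 4, 0.085 without mutant centrocyte library 3 and 0.144 without libraries 3 and 4. That of the B cell receptor list was 0.408 or 0.122 without control centroblast library 1 or 2, 0.178 or 0.0528 without mutant centroblast library 1 or 4, 0.0507 or 0.1 without control centrocyte library 1 or 4, 0.26 without mutant centrocyte library 3, 0.446 without libraries 3 and 4 and 0.0592 with the GC and length offset.

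The genotype change differed between the sexes for 41 genes in centroblasts, 2 higher and 39 lower in females (2830 at an unadjusted p under 0.05), and for 24 genes, 7 higher and 17 lower in females and 17 of them among the 41, with GC and length trends taken out. Examples, named after their values were seen, were Junb (−2.20), Bbc3 (−2.11), Romo1 (−2.09) and Mef2b (−1.49). In control centroblast libraries 1 to 4 the correlation with GC content was −0.62, −0.359, 0.111 and 0.381. Mitochondrial transcripts took 2.727, 1.995, 1.36 and 0.8737% of their counts. Libraries 1 and 2 were male, so sex cannot be told apart from this gradient in centroblasts. In centrocytes 7 genes differed, each higher in females: Adgre1, Hmox1, Ccr3, Fcgr4, Frmd4b, Cd5l and C6. Adgre1, Hmox1, Fcgr4 and Cd5l are macrophage markers, and the female mutant centrocyte libraries are libraries 3 and 4 with the high marker sums, so a sex difference is not shown by these genes. With GC and length trends taken out edgeR called 0 there (1478 at an unadjusted p under 0.05). There were 2 libraries per sex and group.

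Among the genes named in the text 23 of 440 groups of 4 libraries (5.23%) held 1 library far from the others, and chance gives about 1 in 20. In control centrocyte library 1 Cd79b stood at 1960 CPM (the other libraries of the group at 1500 to 1540), Cdc45 at 142 (112 to 115), H2-Aa at 3850 (3300 to 3390) and H2-DMb1 at 176 (196 to 200). In the same library Ly9 stood at 244 CPM (200 to 207), Sesn1 at 36.6 (46.3 to 47.6) and Ube2c at 69.5 (57.2 to 59.3). In control centrocyte library 2 Fcer2a stood at 707 CPM (556 to 581). In control centroblast library 4 Dhrs3 stood at 13.3 CPM (8.47 to 8.74), Gnl3 at 26.4 (40.4 to 41.8), Hhex at 5.06 (3.68 to 3.91), Prc1 at 154 (194 to 198) and Raph1 at 6.53 (11.6 to 12.6). Control centroblast library 1 had Jchain at 1660 CPM (1300 to 1350) and Vpreb3 at 104 (145 to 146), and library 3 had Shank1 at 2.44 (1.39 to 1.47) and Smad1 at 8.97 (5.85 to 6.35). Mutant centroblast library 1 had Kdm6b at 16.8 CPM (12 to 12.6) and library 3 H2-DMb1 at 88 (109 to 112). Mutant centrocyte library 2 had Exo1 at 34.9 CPM (39.6 to 40.3) and Il4i1 at 447 (327 to 345), and library 3 had Iglc2 at 438 (365 to 371) and Ndufb5 at 129 (99.2 to 104).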

How the results depend on the processing

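The GC and length offset, alone and with the block, the sex covariate and the joint removal of mutant centrocyte libraries 3 and 4 were chosen after the results were seen; the other alternatives were planned. Of 178 results for genes named in the text, DESeq2 kept 174 on the same side of the threshold in the same direction (4 newly called), RLE factors 178, no filter 174 (3 lost, 1 newly called), a mean of 1 CPM 174 of 176, the compared groups alone 172 of 175, the replicate block 173, the sex covariate 176, the GC and length offset 176, and no immunoglobulin genes 172 of 173. With each library left out 1432 of 1448 were kept, and 0 reversed. Without mutant centrocyte libraries 3 and 4, 91 of 96 were kept, and Cd86, which was not called, turned from 0.15 to −0.057. Among all called results of the naming rule fewer were kept. The replicate block kept 408 of 476 (85.7%). Without mutant centrocyte libraries 3 and 4, 168 of 240 (70%) stayed called and 1 changed direction. Ezh2 in centroblasts had an adjusted p of 0.0755 with the block, 0.155 with the compared groups alone and 0.0901 without the filter, and in centrocytes 0.0561 and 0.062 with the block and without the filter and 0.157 without mutant libraries 3 and 4.

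In centroblasts the 619 higher genes became 354 with the compared groups alone, 272 with the block, 351 at 1.5-fold, 1382 with the GC and length offset and 940 with block and offset, and the 976 lower genes 599 with the block. In centrocytes the 1123 higher genes became 554 at 1.5-fold, 2139 with the offset, 1762 with block and offset and 495 without mutant libraries 3 and 4, and the 1394 lower genes 729 without them. The 1960 genes lower in control centrocytes became 811 at 1.5-fold, 3148 with the offset and 3017 with block and offset. In mutants the 1360 higher genes became 2099 with the block and 2307 with block and offset, and the 1078 lower genes 586, 2188 and 2456 at 1.5-fold, with the offset and with block and offset. DESeq2 called 1 gene lower for the interaction and 1 gene in opposite directions between the genotype comparisons. Genes higher in both genotype comparisons, 441, became 211 with the block and 1053 with the offset, and those lower in both, 771, became 508 with the block. With the offset 1457 genes were lower in centroblasts and 2003 in centrocytes, and 2736 and 1916 were higher between cell types in controls and mutants, so that the majority direction turned in the last 3 of these comparisons. A fold minimum lowers a count by construction; for the others the cause was not tested.

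Lists called higher and lower with the preset and then the estimated correlation were 7 and 3, then 0 and 0, in centroblasts, 2 and 2, then 0 and 1, in centrocytes, 10 and 4, then 3 and 1, between cell types in controls, 12 and 4, then 4 and 1, in mutants, and 2 and 4, then 0 and 0, for the interaction. Of the lists that camera called, fry called 5 of 10 in centroblasts, 4 of 4 in centrocytes, 14 of 14 and 14 of 16 between cell types in controls and mutants and 0 of 6 for the interaction (smallest adjusted p 0.269), and in this order 1, 1, 6, 4 and 0 further lists. The block gave 4 higher lists in centrocytes. Without mutant centrocyte libraries 3 and 4 the macrophage list, called higher between cell types in mutants, turned (adjusted p = 0.674). With each library left out, 381 to 854 genes were higher and 697 to 1319 lower in mutant centroblasts, with 4 to 7 higher and 2 to 3 lower lists. In mutant centrocytes 619 to 1228 were higher and 971 to 1453 lower, with 2 to 6 higher and 1 to 2 lower lists. Between cell types the ranges were 1743 to 2305 and 1350 to 2069 in controls (8 to 12 and 3 to 4 lists), 1022 to 1370 and 769 to 1002 in mutants (10 to 13 and 3 to 4 lists), and 2 to 5 and 1 to 6 lists for the interaction, with 0 genes by edgeR. Higher lists numbered 4 without control centroblast library 1 in centroblasts, and 6 or 4 without mutant library 1 or 2 in centrocytes, where 1 lower list was left without control library 1. Replicate numbers paired libraries with a correlation of −0.0278 to 0.344 in centroblasts, −0.0886 to 0.123 in centrocytes and −0.0059 to 0.452 in controls.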

Other observations

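The split of the libraries by sex, the correction for GC content and the joint removal of mutant centrocyte libraries 3 and 4 were chosen after the results were seen; the gene lists were planned.

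Some chromatin regulators differed between the zones as single genes. Kdm6b, a demethylase that removes the mark EZH2 writes, was 31.5 ± 3.12 CPM in control centrocytes and 11.2 ± 1.95 CPM in control centroblasts (SD, n = 4), a rise of 1.49 ± 0.15 on the log2 scale, and it rose by 1.13 ± 0.15 in mutants. Smarca4, the ATPase of a chromatin remodelling complex, fell by 1.16 ± 0.14 in controls and 1.20 ± 0.14 in mutants. Among partners of EZH2, Phf1 rose (1.08 ± 0.13 and 0.90 ± 0.13) and Mtf2 fell (−0.90 ± 0.19 and −0.98 ± 0.19). Of 11 members of the complex and its partners 3 rose and 3 fell in controls (4 and 3 adjusted over the list alone; camera adjusted p = 0.665). Of 16 demethylases and lymphoma chromatin regulators 6 rose and 2 fell in controls (7 and 2 adjusted over the list alone; adjusted p = 0.0462, adjusted p = 0.531 with an estimated correlation). That adjusted p was 0.0506 or 0.063 without control centroblast library 1 or 4 and 0.0511, 0.0605 or 0.0699 without control centrocyte library 1, 3 or 4. It was 0.0576 with the replicate block, 0.051 with genes of at least 1 CPM and 0.584 with the GC and length offset, and in mutants, where 5 rose and 2 fell (6 and 2 adjusted over the list alone), the list had 0.0723. The stress gene Atf3 fell by 3.07 ± 0.28 in control and 2.69 ± 0.27 in mutant centrocytes. Ighd (IgD) rose by 1.20 ± 0.15 and 1.10 ± 0.15. Prdm1, the plasma cell regulator, rose by 1.70 ± 0.37 in control centrocytes while Jchain fell by 0.79 ± 0.15.

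Between genotypes some genes of low level rose. Isl1, a homeodomain factor and developmental Polycomb target, rose from 0.264 ± 0.129 to 1.31 ± 0.463 CPM in centroblasts (2.31 ± 0.48) and by 3.18 ± 0.54 in centrocytes. Thy1, known from T cells, rose 6.39-fold to 3.01 ± 0.461 CPM in centroblasts (2.68 ± 0.37) and by 1.92 ± 0.35 in centrocytes. Of 15 T cell markers, Thy1 included, 4 rose in centroblasts (5 adjusted over the list alone) and 3 in centrocytes (3 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.199 and 0.301). Of 60 listed developmental Polycomb targets 12 had enough counts to be tested. In centroblasts 3 of these 12 rose and 1 fell, Gfi1 (−1.22 ± 0.28). The tested targets did not pass as a list (camera adjusted p = 0.981 with an estimated correlation). The other targets had too few counts, so a further fall among them cannot be seen. Vpreb3, a chain that pairs with the pre-B cell receptor, rose by 0.53 ± 0.11 and 0.72 ± 0.11, and Iglc2 by 0.80 ± 0.14 in centroblasts. Basp1 fell by 0.92 ± 0.13 and 0.63 ± 0.13, and Dusp5 by 0.85 ± 0.12 in centroblasts. Dnmt3a rose by 0.57 ± 0.14 in centrocytes (adjusted p = 0.011), where the kinase inhibitor gene Cdkn2c fell by 0.56 ± 0.13.

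Further lists passed in centroblasts with the preset correlation. Of 31 interferon response genes 6 rose, Ifi27l2a by 1.49 ± 0.31, and 1 fell (9 and 1 adjusted over the list alone; adjusted p = 0.032, adjusted p = 0.842 with an estimated correlation), with an adjusted p of 0.138 without control library 1, 0.509 without mutant library 3, 0.0562 with genes of at least 1 CPM and 0.063 with the GC and length offset. By edgeR 0 of 21 MHC class I genes were called (0 adjusted over the list alone, 5 higher at an unadjusted p under 0.05, 1 by DESeq2), and the list was higher (adjusted p = 0.00239, adjusted p = 0.65 with an estimated correlation; 0.137 without control library 1). By edgeR 0 of 36 oxidative phosphorylation genes were called in centroblasts (0 adjusted over the list alone, 2 higher at an unadjusted p under 0.05, 0 by DESeq2), and the list was higher (adjusted p = 0.00383, adjusted p = 0.752 with an estimated correlation). It had 0.0653 without mutant library 2 and 0.159 with GC and length trends taken out.

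In centrocytes against centroblasts, of 21 MHC class I genes 7 rose in controls (adjusted p = 0.0059, adjusted p = 0.553 with an estimated correlation; 0.0867 without control centroblast library 1) and 5 in mutants (adjusted p = 0.0103, adjusted p = 0.585 with an estimated correlation). In mutants that list had 0.0549 without centroblast library 1, 0.0579 without centrocyte library 3 and 0.229 without centrocyte libraries 3 and 4. Of 15 T cell markers 3 rose in mutants (adjusted p = 0.0192, adjusted p = 0.396 with an estimated correlation), with 0.0643 or 0.0603 without centroblast library 1 or 2, 0.0751 or 0.0667 without centrocyte library 3 or 4, 0.352 without both and 0.0513 with genes of at least 1 CPM.

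Gm42418, a gene that overlaps ribosomal RNA repeats, averaged 5059 CPM in control and 8844 CPM in mutant centroblasts and 5539 and 12720 CPM in centrocytes. In control centroblast libraries 1 to 4 the deviation from the mean correlated with GC content across genes, which are not independent replicates, with a Spearman rho of −0.62, −0.359, 0.111 and 0.381. The table lists 92 spike-in controls with 3 reads in all.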
